A study of Mus musculus with 8 samples.

How the data were processed

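Mouse blastocysts at embryonic day 4.5 were profiled by RNA sequencing in 8 libraries of 3 Isca2 genotypes. Isca2 encodes a mitochondrial A-type carrier protein that takes part in building iron-sulfur clusters. The labels give 3 wild-type libraries (WT), 2 knockout libraries (KO, both Isca2 alleles lost) and 3 libraries homozygous for the G77S substitution (G77S). Per the labels' protocols, superovulated heterozygous females were crossed with heterozygous males, embryos were cultured, and full-length mRNA was amplified with a single-cell kit before a transposase-based library preparation. The labels do not give the number of embryos behind each library, their sex, or a batch, day or litter. They name only heterozygous matings and do not say which cross gave the G77S embryos. Nothing in them says that the libraries of a group came from separate litters, so the p-values measure the spread between these libraries, which may be partly technical.

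The deposited values are RSEM gene tables, one per library and not pooled. They hold estimated counts (expected counts, in which reads that map to several genes are split between them), TPM, FPKM and an abundance-weighted length with its effective length, per the file headers. The submitters' processing notes name Trim Galore 0.4.5, STAR 2.6.1c, RSEM 1.3.1 and DESeq2 1.42.1, and the mm10 (GRCm38) build. The annotation release and any filter are not given in the sources used here. The TPM and FPKM values were scaled within each library by the authors, TPM to a fixed total of transcripts and FPKM by transcript length and number of fragments. FPKM was not used here. The difference between the deposited length and effective length was used to read the mean fragment length that the quantification assumed for each library.

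Gene symbols and coordinates came from a GENCODE annotation of GRCm38 (1-based), which matched 55230 of the 55471 gene identifiers in the files (99.6%). The expected counts were rounded to whole numbers. Total expected counts ran from 10323965 to 23842619 per library, and 3 counts in a library correspond to between 0.139 and 0.298 CPM (counts scaled to a common library total, here with TMM factors). Amplified reads carry no molecular identifiers here, so intervals and lower bounds cover counting error only.

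Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the package's group-wise low-count filter (13953 genes kept), 1 model over all 8 libraries with a mean per genotype, the quasi-likelihood F test and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. All adjusted p-values in the report are from this test unless another is named. The standard error of a log2 fold change is its size divided by the square root of F. Levels are TMM-scaled CPM, given as mean ± SD. The common biological coefficient of variation was 0.65, and the prior carried 5.73 degrees of freedom. Where a gene had 0 counts in a group, a fold is a lower bound against 3 counts over the group, and with 1 to 3 counts it is a ratio with its 95% counting interval.

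A total of 32 gene lists (pathways, complexes, lineage markers, other cell types and sex-linked genes) were fixed before the data were examined, and the 29 with at least 3 tested members, sex-linked genes aside, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with a correlation estimated from the data, and with fry. With the estimated correlation no list passed in any comparison, and those adjusted p-values are given beside the calls. The genes named here follow a rule fixed before the data were examined. It takes Isca2, then in each direction up to 10 called genes with the largest change, a mean of at least 10 CPM in the higher group, no overlap between the groups' libraries and a conventional symbol. It adds up to 4 called members of each list (or, with none, up to 2 abundant members as values) and a fixed set of methylation and lineage regulators. Other genes are said to have been chosen after their values were seen.

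The steps were tested on simulated counts for the 13953 genes with 200 genes changed in each of 5 simulations. For KO versus WT, 1.8%, 23.9% and 38.2% of genes changed 2, 4 and 8-fold were called. The shares were 3.9%, 32.8% and 54.2% for G77S versus WT and 1.2%, 22.1% and 45.2% for G77S versus KO. False calls made up 5.8%, 5.3% and 6.6% of all calls in these 3 comparisons. For lists, simulated in KO versus WT only, a planted list was called in 5 of 5 simulations, and 1 of 145 unchanged lists was. Simulated genes varied independently, so this does not give the false call rate of lists whose genes vary together. At this depth and spread a gene without a call may therefore still have changed 4-fold or more.

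Alternatives fixed beforehand were RLE scaling, no filter, a stricter filter (5 CPM in 2 libraries), only the 2 groups compared, the replicate number as a block, DESeq2 1.42.0, limma-trend on log2(TPM + 1), an added threshold of 1 on the absolute log2 fold change, and each library left out. Chosen after the data were seen were a term for Y-linked RNA, only the 6 libraries with Y-linked RNA, and removal of each library's trend over gene length and GC content. On log2(TPM + 1) the median of all genes moved to 0.235 in G77S versus WT and 0.340 in G77S versus KO, from 0.035 and 0.099, so directions there are read relative to that shift. Genes with close copies (Xlr, Zscan4, Gstm, Trim43 and ribosomal protein genes with processed pseudogenes) share reads that RSEM splits, and antisense overlaps cannot be told apart since strand use is not stated, so their values are less certain.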

Results

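RNA was measured in mouse blastocysts at embryonic day 4.5, the stage just before implantation, when the embryo holds epiblast, primitive endoderm and trophectoderm. The series title concerns iron metabolism and an interaction of ISCA2 with TET enzymes, which oxidise methylated cytosine. The design sets embryos without Isca2 (KO, n = 2) and embryos with the G77S form (G77S, n = 3) against wild type (WT, n = 3). Total expected counts were 17320268, 10790670 and 23842619 in WT replicates 1, 2 and 3. They were 18467418 and 21146927 in KO replicates 1 and 2, and 13490295, 12535318 and 10323965 in G77S replicates 1, 2 and 3. Between 14093 and 17534 genes had at least 1 count in a library. The mean fragment length implied by the files was 181.4 to 185.1 bases in the 3 G77S libraries and 242.7 to 291.1 bases in the 5 others. No library of one set fell in the range of the other, so a preparation batch and the G77S genotype cannot be told apart. Correlations of log2 CPM between libraries ran from 0.878 to 0.909 within WT and from 0.923 to 0.933 within G77S, and the KO pair reached 0.898. Between WT and KO they ran from 0.846 to 0.890. RNA of Y-linked genes was near absent in WT replicate 1 (0.346 CPM) and G77S replicate 1 (0.0741 CPM), and both KO libraries carried it.

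Isca2 lies on chromosome 12 from 84773251 to 84775088 on the plus strand (GRCm38) and is protein coding. Its level was 86.9, 173 and 154 CPM in the WT libraries, 4.84 and 6.20 CPM in the KO libraries, and 89.1, 105 and 133 CPM in the G77S libraries. Both KO libraries therefore lay below every other library. Isca2 fell in KO, with a log2 fold change of -4.64 (SE 0.41, adjusted p = 0.00387). In G77S the log2 fold change against WT was -0.34 (SE 0.29, adjusted p = 0.577), and the substitution itself cannot be read from gene counts. The remaining KO counts, 82 and 117, lie above the level of 3 counts.

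**Figure D1:**
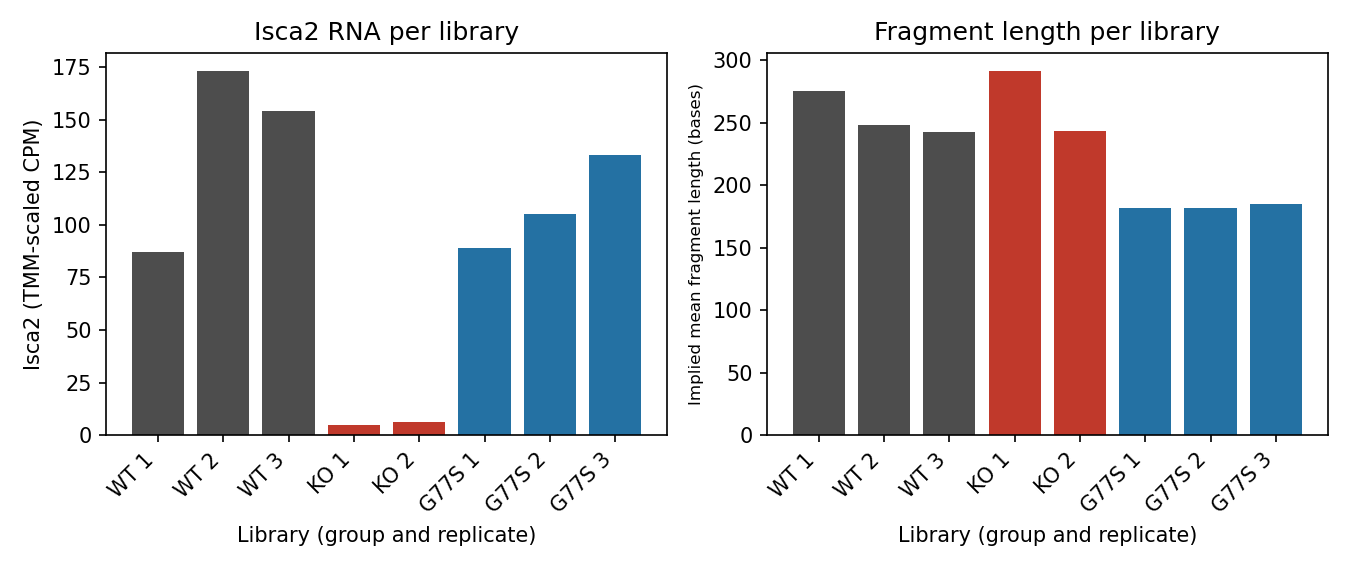
Isca2 RNA (left, TMM-scaled CPM) and implied mean fragment length (right, bases), with 1 bar per library coloured by genotype. Isca2 is 4.84 and 6.20 CPM in the KO libraries and at least 86.9 CPM elsewhere, and the G77S libraries have the shortest fragments, at most 185.1 bases.

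In KO, 11 genes were higher than in WT, among them the primitive endoderm markers Aqp8 and Srgn. Aqp8, a water channel gene, stood at 33.2 ± 7.89 CPM (SD, n = 2) against 0.0186 ± 0.0322 in WT (n = 3), a ratio of 1660 with a 95% counting interval of 297 to 65600 (adjusted p = 0.00801). Srgn, which encodes the proteoglycan serglycin, stood at 166 ± 118 against 1.0 ± 0.872 CPM, a log2 fold change of 7.28 (SE 1.09, adjusted p = 0.0397). Adk, encoding adenosine kinase, rose from 138 ± 29.1 to 761 ± 0.25 CPM (log2 fold change 2.46, SE 0.23, adjusted p = 0.00401). Apoa1, encoding the main protein of high-density lipoprotein, fell from 129 ± 46.7 to 5.25 ± 1.43 CPM (log2 fold change -4.62, SE 0.65, adjusted p = 0.0295). Of 13953 genes, 11 were called higher and 6 lower in KO, and 1819 had an unadjusted p under 0.05.

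The other higher genes were these. Dhrs7, a short-chain dehydrogenase gene on chromosome 12, had 0 counts in WT and 18.7 ± 18.3 CPM in KO, at least 320-fold higher (adjusted p = 0.0295). Rcn1, a calcium-binding protein gene of the endoplasmic reticulum, had a ratio of 925 (165 to 36600, adjusted p = 0.0488). P4ha1, a collagen prolyl hydroxylase subunit gene, had a ratio of 220 (74.9 to 1070, adjusted p = 0.0261). Gstm1, a glutathione transferase gene, rose by 3.75 (SE 0.55, adjusted p = 0.0389) and Adhfe1, an alcohol dehydrogenase gene, by 3.74 (SE 0.43, adjusted p = 0.0125) on the log2 scale. Utf1, a chromatin factor of pluripotent cells, rose by 3.33 (SE 0.46, adjusted p = 0.0295), and Mrpl17, a mitochondrial ribosomal protein gene, by 1.53 (SE 0.24, adjusted p = 0.0451). Nsmce1, a subunit gene of the SMC5/6 complex, was lower at -1.69 (SE 0.24, adjusted p = 0.0343). Alppl2, an alkaline phosphatase gene, had 1 to 3 counts in KO and a WT to KO ratio of 412 (114 to 3400, adjusted p = 0.0397). The rest, named after their values were seen, were Efcab10, higher (adjusted p = 0.0271), and Gm13102 and Slc35e4, lower (adjusted p = 0.0232 and 0.0416).

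The primitive endoderm list had the largest median among the lists called in KO. Of its 23 tested genes, 2 were called higher, 0 lower and 21 not called. Adjusted over the list alone, 12 were higher and 2 lower. The median log2 fold change was 2.10 (camera adjusted p = 9.83e-10; adjusted p = 0.428 with an estimated correlation). Its size depends on the scale, since the median was 0.39 on log2(TPM + 1), while the 16 members left by the stricter filter had 1.85. Of the 23 members, 6 had 0 to 3 counts in 1 group, and setting them to their bounds or ratios left the median at 2.10. Gata6, a regulator of primitive endoderm, had 27.4 ± 0.905 CPM in KO and 20 ± 3.10 in WT (adjusted p = 0.606). Lamb1, a laminin gene chosen after its values were seen, had 22.0 ± 2.99 and 5.13 ± 0.513 CPM (adjusted p = 0.106). The epiblast list had 29 tested genes, of which Utf1 alone was called, and 7 higher and 2 lower adjusted over the list alone (median 0.68, camera adjusted p = 0.00406; adjusted p = 0.72 with an estimated correlation). This direction is not settled, since the median was -0.16 under the stricter filter, with 9 of 19 members positive, and 0.41 without KO replicate 2. Members went both ways. Nanog, a naive pluripotency factor, had 40.4 ± 18.4 CPM in KO and 261 ± 38.1 in WT (log2 fold change -2.69, SE 0.44, adjusted p = 0.0529), and Pou5f1 had -0.94 (adjusted p = 0.413). Sox2 had 0 counts in all WT libraries and 0.869 ± 0.644 CPM in KO (adjusted p = 0.232), and Sox17 had 0 counts in WT and 0.982 ± 0.115 CPM in KO (adjusted p = 0.342).

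**Figure D2:**
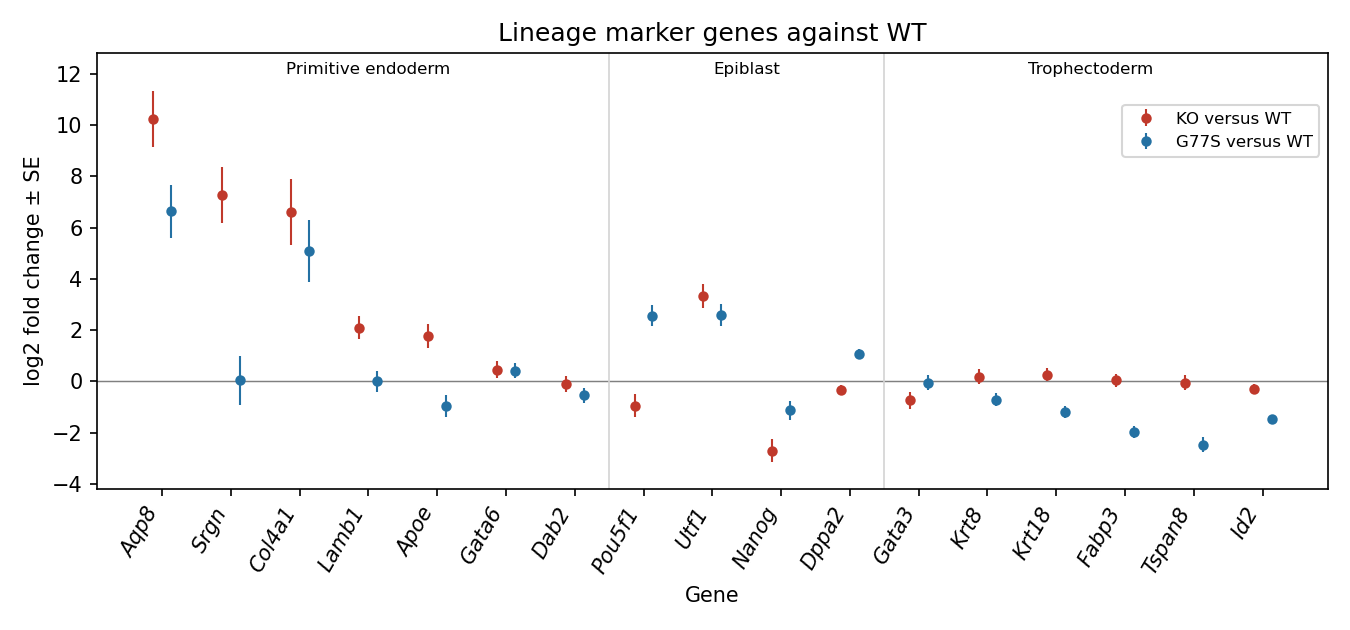
Fitted log2 fold change with its standard error (y axis) of lineage marker genes (x axis) in KO and G77S against WT, some of them chosen after their values were seen. The genes shown are part of each list and do not give its spread. In KO the primitive endoderm list had 17 positive and 6 negative members, the lowest at -5.6 and not shown. In G77S the trophectoderm list had 7 positive and 22 negative members. Of the positive ones, Cldn6 (2.22) and Cdx2 (0.43) are not shown. Aqp8 (10.21) and Srgn (7.28) are the highest KO points, and Aqp8 has too few WT counts for its fitted value to be read as a size.

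The trophectoderm list had a median of -0.68 over 29 tested genes, 8 positive and 21 negative (camera adjusted p = 0.011; adjusted p = 0.72 with an estimated correlation). It held 0 called genes, 0 also when adjusted over the list alone. The median was -0.38 without WT replicate 1, -0.32 without KO replicate 2 and -0.33 with a term for Y-linked RNA. Cdx2, Gata3 and Krt8, trophectoderm genes, had log2 fold changes of -0.79, -0.74 and 0.19 (adjusted p = 0.663, 0.362 and 0.851). The 2-cell list had a median of -0.56 over 12 genes, with 0 called and 4 lower adjusted over the list alone (camera adjusted p = 0.0285; adjusted p = 0.72 with an estimated correlation). The fall lay in KO replicate 2, with a mean log2 CPM of 2.94 against 4.52 in KO replicate 1 and 4.01 to 4.74 in WT, and the call was lost without KO replicate 2 and without WT replicate 3 (adjusted p up to 0.587). Its most abundant members were Calcoco2 at -1.61 (adjusted p = 0.0832) and Pramel6 at -1.39 (adjusted p = 0.202). Among translation and respiration lists, cytosolic ribosomal proteins had a median of 0.25, with 72 of 77 genes positive (camera adjusted p = 0.000135; adjusted p = 0.764 with an estimated correlation), and mitochondrial ribosomal proteins 0.18, with 61 of 78 positive (camera adjusted p = 0.00189; 0.764 as the adjusted p with an estimated correlation). Complex I and II subunits had a median of 0.26, with 32 of 40 positive (camera adjusted p = 0.00645; adjusted p = 0.764 with an estimated correlation). The mitochondrial-encoded subunits had 0.25, with 11 of 13 positive (camera adjusted p = 0.0487; adjusted p = 0.72 with an estimated correlation). Once each library's trend over gene length and GC content was removed, these 4 medians were 0.08, 0.08, 0.12 and -0.20, and that of the trophectoderm list was -0.38. Adjusted over the list alone, these 4 lists held 0, 1, 1 and 0 higher genes and 0 lower ones. The calls of the trophectoderm, complex I and II, mitochondrial ribosomal and mitochondrial-encoded lists were each lost without WT replicate 1 and without KO replicate 2, and the cytosolic ribosomal call without WT replicate 1 (adjusted p = 0.0502). Mitochondrial transcripts took 4.66 and 5.03% of counts in KO and 3.35 to 4.03% in WT. Pseudogenes took 2.92 and 3.11% in KO and 1.87 to 2.34% in WT, and the 10 most abundant genes 11.47 and 13.22% against 10.2 to 10.92%.

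Lists of iron-sulfur assembly, iron handling and DNA methylation genes were not called in KO. Their RNA levels do not measure cluster assembly, iron status or methylation. In the mitochondrial iron-sulfur assembly list, Isca2 alone of 19 tested genes was called (median 0.32, camera adjusted p = 0.163). In the iron handling list 0 of 21 genes were called (median -0.19, camera adjusted p = 0.901). Ftl1, encoding ferritin light chain, had 24230 ± 9338 CPM in KO and 9881 ± 5283 in WT (adjusted p = 0.285), and Fth1, encoding the heavy chain, had a log2 fold change of 0.02 (adjusted p = 0.996). Of 27 DNA methylation genes 0 were called (median -0.01, camera adjusted p = 0.901), with 1 higher and 2 lower adjusted over the list alone. Tet1, Tet2 and Tet3 had log2 fold changes of -0.01, -1.25 and -1.26 (adjusted p = 1, 0.238 and 0.733). Dnmt1, Dnmt3a, Dnmt3b and Dnmt3l, DNA methyltransferase family genes, had 0.17, 0.37, -0.11 and 0.03 (adjusted p = 0.966, 0.938, 0.972 and 0.995). Dppa3, which protects the maternal genome from demethylation, had -1.34 (adjusted p = 0.147). The 21 lists not called in KO had camera adjusted p-values from 0.0992 to 0.989. Without KO replicate 2 the counts were 0 higher and 0 lower with edgeR, while 1366 genes had an unadjusted p under 0.05, without WT replicate 2 they were 1 and 1, and DESeq2 called 305 higher and 345 lower with all libraries.

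More genes were called between G77S and WT than between KO and WT. These counts do not rank the effects, since KO had 2 libraries and the G77S libraries also differed in fragment length. Of simulated 4-fold changes, 32.8% were called in G77S versus WT and 23.9% in KO versus WT. Among abundant genes, Adh1, encoding an alcohol dehydrogenase, fell from 10400 ± 2335 CPM in WT (n = 3) to 406 ± 66.2 in G77S (n = 3), a log2 fold change of -4.68 (SE 0.24, adjusted p = 1.17e-05). Fabp3, a fatty acid binding protein gene of the trophectoderm list, fell from 18200 ± 2008 to 4606 ± 1445 CPM (log2 fold change -1.98, SE 0.23, adjusted p = 0.00332). Pou5f1, encoding the pluripotency factor OCT4, rose from 6.51 ± 1.75 to 38.6 ± 13.3 CPM (log2 fold change 2.57, SE 0.41, adjusted p = 0.0104). Slc40a1, encoding the iron exporter ferroportin, fell from 100 ± 53.7 to 3.57 ± 1.39 CPM (log2 fold change -4.81, SE 0.86, adjusted p = 0.0156). Of 13953 genes, 182 were higher and 291 lower, and limma-trend on log2(TPM + 1) gave 1178 higher and 288 lower.

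The largest changes given here are among called genes within the naming rule's limits on level, overlap and symbol. The largest increases were in genes nearly absent from WT. Tat, encoding tyrosine aminotransferase, had a ratio of 1540 (275 to 60800, adjusted p = 0.00722) and Hspb8, a small heat shock protein gene, 1080 (193 to 42700, adjusted p = 0.0216). Htr5b, a serotonin receptor gene, had 512 (91.3 to 20300, adjusted p = 0.00337) and Mest, an imprinted gene, 415 (142 to 2020, adjusted p = 0.00368). Mgarp, a mitochondrial protein gene, rose by 4.78, Gpx2, a glutathione peroxidase gene, by 4.66, Scd3, a desaturase gene, by 4.51 and Urah by 4.29 on the log2 scale (adjusted p = 0.00487, 0.00415, 0.041 and 0.00754). Ly6a rose by 3.75 and Ube2l6 by 3.36 (adjusted p = 0.017 and 0.0472). The largest decreases were Wls, a carrier for WNT secretion (-8.22), Nupr1, a stress-induced transcription regulator (-7.18), Slc7a3, a cationic amino acid transporter gene (-6.64), and Stk39 (-6.22), with adjusted p = 0.00337, 0.00431, 0.00868 and 0.0369. Tspan33 and Ltc4s, a leukotriene synthase gene, each fell by 5.33, S100a1 by 5.30 and Prnd by 5.04 on the log2 scale (adjusted p = 0.0314, 0.00241, 0.00192 and 0.0271).

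Lineage lists moved in opposite directions in G77S in the main fit. On log2(TPM + 1), relative to the median of all genes there, the trophectoderm median was -0.80. On that scale the primitive endoderm and epiblast medians were 0.12 and 0.20, smaller than in the main fit. Under the stricter filter the epiblast median was 0.53. The trophectoderm list had 1 gene called higher, 9 lower and 19 not called, and 2 higher and 14 lower adjusted over the list alone (median -0.87, camera adjusted p = 5.07e-08; adjusted p = 0.428 with an estimated correlation). Tspan8 fell by 2.46 and Id2 by 1.48 (adjusted p = 0.00332 and 0.00337), Krt18, a keratin gene chosen after its values were seen, by 1.20 (adjusted p = 0.0222), and Cldn6, a tight junction gene, rose by 2.22 (adjusted p = 0.0106). Cldn6 is also a member of the formative and primed epiblast list. Gata3 and Cdx2, transcription factor genes, had -0.04 and 0.43 (adjusted p = 0.963 and 0.736), and Krt8 had -0.71 (adjusted p = 0.143). The placental list had 5 positive and 5 negative genes with Plac1 (-2.86, adjusted p = 0.00337) and Slc38a4 (-1.24, adjusted p = 0.0301) called lower (camera adjusted p = 0.243). The epiblast list had 4 genes higher, 0 lower and 25 not called, and 10 higher and 2 lower adjusted over the list alone (median 1.07, camera adjusted p = 0.00211; adjusted p = 0.673 with an estimated correlation). Its median was 0.19 without G77S replicate 1, with 16 of 28 members positive, and 0.29 in the 6 libraries with Y-linked RNA, where the call was lost (adjusted p = 0.0752). Besides Pou5f1 these were Utf1 (2.59, adjusted p = 0.0118), Dppa2 (1.07, adjusted p = 0.012) and Dppa4 (290 ± 22.5 against 109 ± 25.1 CPM, adjusted p = 0.0123), and Nanog had -1.13 (adjusted p = 0.107). Sox2 and Sox17 had 0 counts in WT and 0.406 ± 0.436 and 0.863 ± 1.5 CPM in G77S (adjusted p = 0.157 and 0.205). In the primitive endoderm list Aqp8 (ratio 143, 25.2 to 5700, adjusted p = 0.00903) and Col4a1, a basement membrane collagen gene (5.09, SE 1.20, adjusted p = 0.0478), were higher and 21 genes were not called (6 higher and 1 lower adjusted over the list alone, median 1.16, camera adjusted p = 0.0341; adjusted p = 0.673 with an estimated correlation), and Gata6 had 0.42 (adjusted p = 0.472). The 2-cell list, which shares Dppa2 and Dppa4 with the epiblast list, had these 2 genes higher of 12, also adjusted over the list alone (median 0.80, camera adjusted p = 0.0425; adjusted p = 0.673 with an estimated correlation). The primitive endoderm and 2-cell calls were each lost in 10 of 15 alternatives, and the primitive endoderm median was 0.26 under the stricter filter (10 of 16 positive), 0.43 without G77S replicate 1 and 0.52 in the 6 libraries with Y-linked RNA.

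The nuclear-encoded respiratory chain lists were lower in G77S than in WT. Complex I and II subunits had 0 genes higher, 4 lower and 36 not called, 6 lower adjusted over the list alone (median -0.49, camera adjusted p = 1.06e-06; adjusted p = 0.673 with an estimated correlation). The called genes were Sdhb (-1.19, adjusted p = 0.032), which encodes the iron-sulfur subunit of complex II, Ndufa10 (-0.85, adjusted p = 0.0373), Ndufs4 (-1.16, adjusted p = 0.0378) and Ndufa1 (-1.20, adjusted p = 0.0496). The mean log2 CPM of this list was 7.99 in WT replicate 1, within the G77S range of 7.77 to 8.05, and 8.58 and 8.5 in the other WT libraries. Complex III, IV and V subunits and cytochrome c had Cycs lower (-1.05, adjusted p = 0.0454), 0 higher and 36 not called, 7 lower adjusted over the list alone (median -0.41, camera adjusted p = 0.000211; adjusted p = 0.673 with an estimated correlation). Here too WT replicate 1, with a mean log2 CPM of 9.04, lay within the G77S range of 8.83 to 9.14, and the other WT libraries had 9.56 and 9.53. The mitochondrial-encoded subunits were not called (median 0.07, camera adjusted p = 0.822). In the tricarboxylic acid cycle and lipoylation list Suclg1 fell (-0.89, adjusted p = 0.0438) and Gcsh, a glycine cleavage protein gene, rose (0.76, adjusted p = 0.0447), with a camera adjusted p of 0.324. Cytosolic ribosomal protein genes had 2 higher and 75 not called, Rps15a (0.94) and Rpl21 (0.77), and 20 higher adjusted over the list alone (median 0.41, camera adjusted p = 1.15e-07; adjusted p = 0.673 with an estimated correlation). Mrpl41 fell (-1.26, adjusted p = 0.00945) and Mrpl17 rose (1.22, adjusted p = 0.0151) among mitochondrial ribosomal protein genes.

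Stress response genes moved in both directions. The list of ATF4 targets of the integrated stress response had 1 gene higher, 6 lower and 26 not called, and 2 higher and 10 lower adjusted over the list alone (median -0.84, camera adjusted p = 0.00211; adjusted p = 0.673 with an estimated correlation). Its mean log2 CPM was 3.20 in WT replicate 1, within the G77S range of 2.87 to 3.61, and the call was lost without G77S replicate 3 (adjusted p = 0.0504). Besides Nupr1, Asns, encoding asparagine synthetase, fell by 3.53, Aldh18a1, of proline synthesis, by 2.39 and Ddit3, encoding CHOP, by 2.03 (adjusted p = 0.0118, 0.012 and 0.0173). In the NRF2 and lipid peroxide list 4 genes were higher, 1 lower and 17 not called, and 7 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.243). Gclm, for glutathione synthesis, rose by 2.76, Cat, encoding catalase, by 2.42 and Gsr, encoding glutathione reductase, by 2.30 (adjusted p = 0.00495, 0.00903 and 0.00993), and Gpx1 fell by 1.32 (adjusted p = 0.00783). Cell cycle genes had 2 higher, 0 lower and 35 not called, 6 higher adjusted over the list alone (median 0.58, camera adjusted p = 0.000638; adjusted p = 0.673 with an estimated correlation), with Rrm2 at 1.19 and Mcm7 at 1.5 (adjusted p = 0.0164 and 0.0364). Iron-sulfur enzymes outside mitochondria had 0 called of 18, 0 adjusted over the list alone, and 14 positive (median 0.68, camera adjusted p = 0.0273; adjusted p = 0.673 with an estimated correlation), and the call was lost without G77S replicate 2 or replicate 3 (adjusted p up to 0.0998) and in the fit of only these 2 groups.

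Single members of other lists were also called in G77S. Ciao2a, of cytosolic iron-sulfur assembly, fell by 1.22 (adjusted p = 0.0165). Gadd45a, a DNA damage response gene kept in the DNA methylation list, had 0 counts in WT and was at least 45.3-fold higher (adjusted p = 0.0419). P4ha1 had a ratio of 146 (49.7 to 714, adjusted p = 0.00515) and Pgam1, a glycolytic enzyme gene, rose by 1.37 (adjusted p = 0.0373). Pmaip1, encoding NOXA, rose by 2.43 (adjusted p = 0.0207) and Tex19.1, a germline gene, by 1.75 (adjusted p = 0.0484). Besides Mest, the imprinted list held Xlr4c (-1.78, adjusted p = 0.00495) and Xlr3b (-1.22, adjusted p = 0.0253), whose close copies share reads. Khdc3, a maternal gene, rose by 1.03 (adjusted p = 0.0144) and Hsd17b1, of the granulosa list, had a ratio of 154 (27.2 to 6140, adjusted p = 0.0253). Tet1, Tet2 and Tet3 had log2 fold changes of 1.39, -0.14 and -2.69 (adjusted p = 0.258, 0.881 and 0.218). Dnmt1, Dnmt3a, Dnmt3b and Dnmt3l had -1.10, 0.27, -0.25 and 0.50 (adjusted p = 0.368, 0.909, 0.829 and 0.496). The 19 lists not called had camera adjusted p-values from 0.243 to 0.954. All calls of this comparison carry the fragment length difference, 183 ± 2.01 bases in G77S against 255 ± 17.6 in WT, and the G77S libraries also had more genes detected (15933 to 17534 against 14093 to 15742) and less in their 10 most abundant genes (7.03 to 8.24% of counts against 10.2 to 10.92%). Without G77S replicate 1 there were 31 higher genes, and without G77S replicate 2 there were 51 lower ones.

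**Figure D3:**
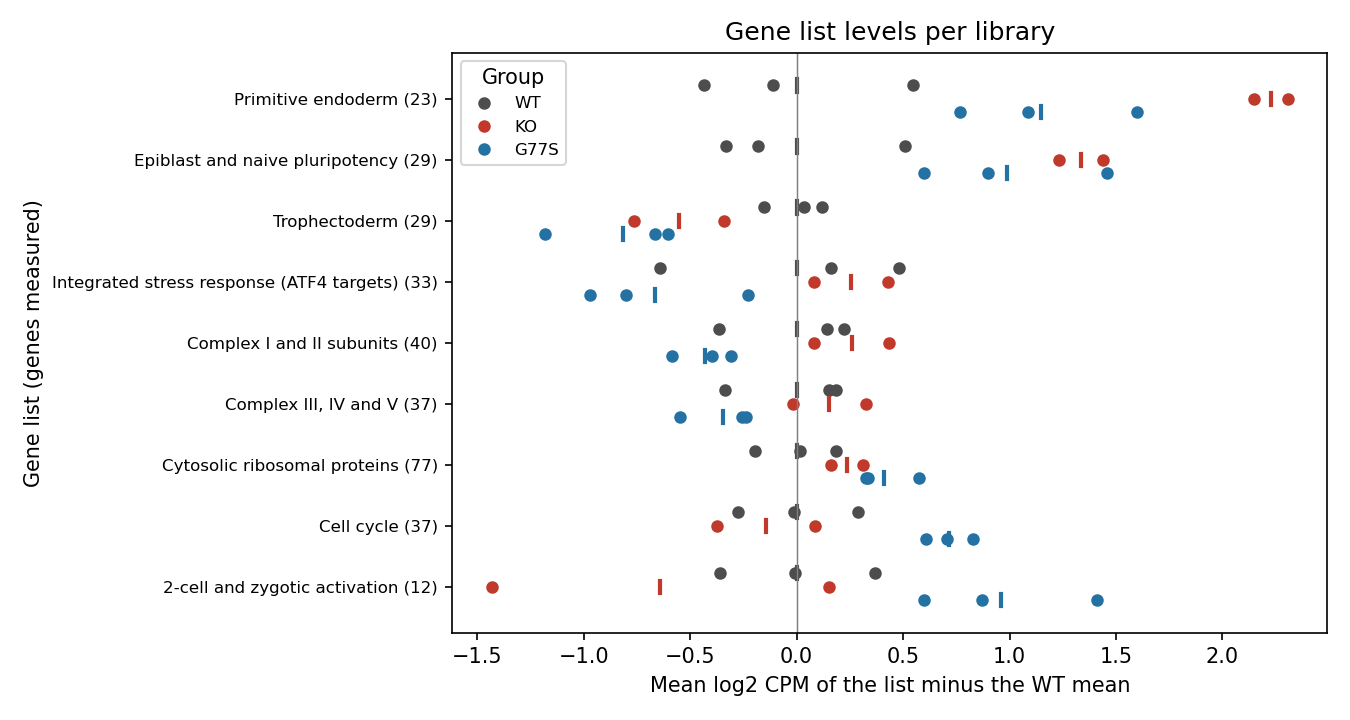
Mean log2 CPM of each gene list minus its WT mean (x axis) for 9 lists (y axis), with dots for libraries and ticks for group means. For primitive endoderm, both KO libraries (3.59 and 3.43 before subtraction) and the G77S libraries (2.05 to 2.88) lie above all WT libraries (at most 1.83). The 2-cell and epiblast lists share Dppa2 and Dppa4.

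Set against KO directly, the G77S libraries had higher cell cycle and 2-cell lists and lower nuclear-encoded respiratory chain lists, none of them past the threshold with an estimated correlation (adjusted p = 0.513 for each). Isca2 was higher (log2 fold change 4.30, SE 0.40, adjusted p = 0.00099). Adh1 was 406 ± 66.2 CPM in G77S (n = 3) and 15540 ± 831 in KO (n = 2), a log2 fold change of -5.26 (SE 0.25, adjusted p = 6.22e-06). Sdhb was 389 ± 40.1 against 1234 ± 135 CPM (log2 fold change -1.67, SE 0.28, adjusted p = 0.0102), and Pou5f1 was 38.6 ± 13.3 against 3.38 ± 0.689 CPM (log2 fold change 3.51, SE 0.51, adjusted p = 0.00614). Of 13953 genes 246 were higher and 339 lower, and limma-trend on log2(TPM + 1) gave 1543 and 306.

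Complex I and II subunits had 0 genes higher, 6 lower and 34 not called, and 19 lower adjusted over the list alone (median -0.68, camera adjusted p = 1.21e-11; adjusted p = 0.513 with an estimated correlation). They included Ndufs4 (189 ± 29.7 against 507 ± 119 CPM, adjusted p = 0.0204), Ndufa12 (-1.15, adjusted p = 0.0204) and Ndufb5 (-1.26, adjusted p = 0.0208). Complex III, IV and V subunits had 3 lower and 34 not called, Uqcr11 (-1.61), Cycs (-1.26) and Uqcrq (-1.24), with 1 higher and 11 lower adjusted over the list alone (median -0.60, camera adjusted p = 3.27e-06; adjusted p = 0.513 with an estimated correlation). On log2(TPM + 1) the Cycs value was 0.02, below the median of 0.340 over all genes there. The tricarboxylic acid cycle list, given next, shares Sdha, Sdhb, Sdhc and Sdhd with the complex I and II list, so their calls are not independent. The tricarboxylic acid cycle list had 2 lower, Sdhb and Suclg1 (-1.16), with 3 higher and 8 lower adjusted over the list alone (median -0.36, camera adjusted p = 0.0165; adjusted p = 0.513 with an estimated correlation), and mitochondrial ribosomal proteins 3 lower, Mrpl41 (-1.83), Mrpl23 (-1.38) and Mrpl1 (-1.25), 3 also adjusted over the list alone (median -0.17, camera adjusted p = 0.00671; adjusted p = 0.637 with an estimated correlation). The ATF4 target list had 3 lower, Nupr1 (-7.62), Asns (-3.57) and Ddit3 (-2.28), with 1 higher and 6 lower adjusted over the list alone (median -0.39, camera adjusted p = 0.00406; adjusted p = 0.513 with an estimated correlation). On log2(TPM + 1) the medians of these last 3 lists were 0.20, 0.25 and 0.10, where the median of all genes was 0.340. The tricarboxylic acid cycle and ATF4 calls were lost without KO replicate 1 (adjusted p = 0.191 and 0.0802), and the mitochondrial ribosomal call without KO replicate 2 and with a term for Y-linked RNA. With each library's trend over gene length and GC content removed, the medians of the complex I and II, complex III to V, mitochondrial ribosomal and ATF4 lists were -0.54, -0.35, -0.09 and -0.93. The mitochondrial-encoded mt-Co1 (-1.34, adjusted p = 0.0103) and mt-Co3 (-1.05, adjusted p = 0.0276) fell, and their list did not pass (camera adjusted p = 0.0651), with a median of -0.38 that turned to 0.16 once that trend was removed.

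Cell cycle genes had 4 higher, 0 lower and 33 not called, and 6 higher adjusted over the list alone (median 0.85, camera adjusted p = 1.3e-05; adjusted p = 0.513 with an estimated correlation), with Plk1 (2.99), Mcm7 (2.21), Aurka (1.98) and Rrm2 (1102 ± 178 against 411 ± 43.9 CPM). The cell cycle median was 0.54 with the length and GC trend removed. The 2-cell list had 3 higher and 9 not called, Pramel6 (2.0), Calcoco2 (1.95) and Dppa2 (1.39), and 6 higher adjusted over the list alone (median 1.67, camera adjusted p = 0.00023; adjusted p = 0.513 with an estimated correlation). The primitive endoderm list had 1 higher, 5 lower and 17 not called, and 2 higher and 6 lower adjusted over the list alone (median -0.93, camera adjusted p = 0.00672; adjusted p = 0.513 with an estimated correlation). Srgn (-7.24), Apoe (-2.72) and Aqp8 (-3.58) fell and Lrp2, encoding megalin, rose (2.36). The trophectoderm list had 1 higher, 5 lower and 23 not called, and 3 higher and 13 lower adjusted over the list alone (median -0.55, camera adjusted p = 0.00672; adjusted p = 0.513 with an estimated correlation), with Fabp3 (-2.02), Tspan8 (-2.42) and Id2 (-1.19) lower and Cldn6 (3.31) higher. Without KO replicate 1 the primitive endoderm and trophectoderm calls were lost (adjusted p = 0.114 and 0.154, medians -0.64 and -0.21), and without G77S replicate 2 the trophectoderm call was lost with a median of -0.15. Plac1 of the placental list fell (-2.72, adjusted p = 0.00406). The epiblast list was not called (median -0.18, camera adjusted p = 0.889), though Spic rose (4.88, adjusted p = 0.0175) and Nanog had 1.56 (adjusted p = 0.065).

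Other genes called between G77S and KO were as follows. Mest was at least 300-fold higher (adjusted p = 0.00506), and Alppl2, Osbpl6 and Slc35e4 had ratios of 1230 (339 to 10100), 250 (68.9 to 2070) and 140 (47.7 to 682). Trim43b (7.92), whose family members share reads, Tat (5.04), Nlrp4c (5.03), Naa60 (5.01) and Ggt1 (4.74) were higher. Wls (-8.61), Cyp26a1, which degrades retinoic acid (-7.26), Rcn1 (-6.95), S100a1 (-6.76), Ubd (-6.66) and Lrrc34 (-6.06) were lower, and Qpct had a KO to G77S ratio of 166 (56.4 to 808). In iron-sulfur and iron lists, Nfu1, an iron-sulfur cluster carrier gene, fell by 0.99, Ndufab1 by 1.24 and Ciao2a by 1.27, while Dph1 rose by 4.61 and Pcbp1 by 1.39. Dppa3 rose by 1.92 (adjusted p = 0.0126) and Idh2, which makes 2-oxoglutarate, fell by 1.67 (adjusted p = 0.0163). Gpx1 fell by 1.49, and Gsr and Gclm rose by 2.25 and 1.67. Xlr4c, Xlr3b and Xlr4b fell by 1.90, 1.90 and 1.72. Gtse1 (2.59), Tex19.1 (2.41), Khdc3 (1.23), Mvd (3.17) and Rpl37a (0.99) rose and Ifi27 fell (-4.26). Tet1, Tet2 and Tet3 had 1.41, 1.11 and -1.42 (adjusted p = 0.306, 0.16 and 0.548). The 20 lists not called had camera adjusted p-values from 0.0651 to 0.889. Without KO replicate 2, 57 genes were higher, and without G77S replicate 2, 91 were lower.

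The KO and G77S comparisons use the same WT libraries. Of the called genes, 6 were higher in both, Aqp8, Dhrs7, P4ha1, Efcab10, Mrpl17 and Utf1, where independent lists would share 0.143 and 20 simulations of unchanged groups shared 0. Neither number gives the level that chance would reach for the 6, since the first leaves out the shared WT libraries and the second has no changed genes to call. Without WT replicate 2 or KO replicate 2 the number was 0, and without WT replicate 1 it was 17. With edgeR 0 genes were lower in both, where 191 had an unadjusted p under 0.05 in both and DESeq2 called 64, and beside the 6 higher genes these numbers were 369 and 108. Across 13953 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.418, and simulated unchanged groups gave 0.434. Their covariance was 1.462 against 0.656 in simulation, a difference of 0.806. It ran from 1.342 to 2.319 with single libraries left out. Under the stricter filter, which tests fewer genes and was not simulated, it lay below 0.656. The simulation gave every group the same spread for a gene, while WT libraries correlated less (0.878 to 0.909) than G77S libraries (0.923 to 0.933). More spread in the shared WT libraries would raise the covariance without a shared effect. The difference of 0.806 therefore cannot decide whether effects are shared. The Spearman correlation was 0.3 against 0.403 in simulation, and 59% of genes had the same sign against 64.8%. The simulation has no changed genes, and changes in 1 genotype alone would lower both values. These ranks and signs therefore cannot decide whether effects are shared. The WT libraries are too few to be divided, so part of the shared calls may come from the shared controls.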

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

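The batch test was chosen only after the result was seen, the length and GC removal and the Y-linked term are settings chosen after the data were seen, and the remaining tests were written down once the most changed genes, but not the values tested, had been seen. The trophectoderm test named the placental list beforehand, but the share of its genes that had to be negative replaced a negative median after the median of -0.03, which would have met the prediction, was seen. In 4 gene lists the 2 mutant groups had medians of opposite sign against WT and differed in the direct comparison of G77S with KO. Complex I and II subunits had a median of 0.26 in KO and -0.49 in G77S, and the direct camera test gave an adjusted p of 1.21e-11. Its KO call was lost in 6 of 15 alternatives, and its mean log2 CPM in KO, 8.44 and 8.79, lay near the 8.58 and 8.5 of WT replicates 2 and 3, with 7.99 in WT replicate 1. Complex III, IV and V subunits had 0.17 and -0.41 (adjusted p = 3.27e-06), but in KO the list was not called (adjusted p = 0.141) and its median was -0.01 with the length and GC trend removed. The 2-cell list had -0.56 and 0.80 (adjusted p = 0.00023), with the KO fall in replicate 2 (mean log2 CPM 2.94, against 4.52 in replicate 1 and 4.01 to 4.74 in WT). Cell cycle genes had -0.27 and 0.58 (adjusted p = 1.3e-05), and were not called in KO (adjusted p = 0.141). The opposite sign in KO is therefore not established for any of the 4 lists. With an estimated correlation the adjusted p was 0.513 for each of these 4 lists. All 4 compare libraries of different fragment length.

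The first pattern is the set of 473 genes called between G77S and WT. Against a smooth trend over gene length and GC content as the cause of most calls, 89% of the calls (421 genes) remained in the same direction after each library's trend was removed. The removal covers only such a trend, so effects of fragment length on single genes stay open. A separate preparation batch stays open, since 57.6 bases part the longest G77S fragment length from the shortest of the other libraries and genotype and batch cannot be told apart. A lower share of trophectoderm cells also stays open: the lower of the epiblast and primitive endoderm medians lay 1.94 above the trophectoderm median on the log2 scale (less without G77S replicate 1, with epiblast at 0.19 and trophectoderm at -0.98), yet Gata3 had -0.04 where Fabp3 had -1.98 and the placental list had 5 positive and 5 negative genes. The genotype itself stays open as the biological explanation. Among the 10 splits of these 6 libraries only 1, the real one, called as many genes, and 10 splits are too few for a share under 0.05. The real split called 452 with edgeR on the 13953 genes of the main filter, while the fit of only these 2 groups given below tested 11827 under its own filter. The highest other split called 0, with 279 to 787 genes at an unadjusted p under 0.05 in the other splits.

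The second pattern is the higher primitive endoderm list in KO, with a median of 2.10, 1.85 over the 16 genes of the stricter filter and 0.39 on log2(TPM + 1). The G77S libraries also lay above all WT libraries in the mean log2 CPM of this list (2.05 to 2.88, against at most 1.83). Sex of the embryos as the whole cause is argued against by a median of 2.18 with a term for Y-linked RNA. The median was 2.17 without WT replicate 1. It could hardly have been much lower, since that library had the highest WT level of the list (mean log2 CPM 1.83, against 1.17 and 0.85). WT replicate 1 was also the only library of this comparison without Y-linked RNA, so both checks rest largely on the same library. A larger share of primitive endoderm cells stays open. Of the 23 tested markers 73.9% were higher in KO, but these are the values that make up the pattern, so they cannot decide its cause. Gata6 had 0.45 and Dab2, chosen after its values were seen, had -0.10, and higher RNA per cell would also raise markers. With 2 KO libraries and no embryo numbers in the labels, a difference in developmental stage was not tested.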

How the results depend on the processing

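The Y-linked RNA, 6-library and length and GC settings were chosen after seeing the data. RLE scaling, the fold threshold and removal of the length and GC trend kept all 6 counts of called genes within 1.5 times. Counts below are higher then lower, in the order KO versus WT, G77S versus WT and G77S versus KO, beside 11 and 6, 182 and 291, and 246 and 339. No low-count filter gave 285 and 262, 598 and 738, and 619 and 792. The stricter filter, which tests fewer genes, gave 34 and 26, 325 and 421, and 391 and 455. Fits of only the 2 groups compared, with fewer libraries, gave 8 and 3, 326 and 340, and 489 and 520. DESeq2 gave 305 and 345, 714 and 824, and 853 and 847, and limma-trend on log2(TPM + 1) gave 57 and 38, 1178 and 288, and 1543 and 306. The Y-linked term gave 25 and 7, 212 and 315, and 173 and 270, and the 6 libraries 21 and 11, 101 and 213, and 153 and 333. The replicate block gave 4 and 4, 154 and 257, and 251 and 349, with a correlation of 0.375 between the mutant effects and 1 gene higher and 2 lower in both. Same-number deviations from the group means correlated between -0.021 and 0.071. With 2 or 3 libraries in a group such deviations are tied together, so pairing by replicate number is neither shown nor excluded. For gene lists, 8, 10 and 9 were called, and with an estimated correlation 0, 0 and 0 (1, 1 and 2 at an unadjusted p under 0.05), with fry 0, 0 and 0 (4, 7 and 8 unadjusted), and in KO 4 with the Y-linked term and 4 in the 6 libraries. Under the stricter filter the correlation was 0.346, the covariance 0.420, and 17 genes were higher and 7 lower in both. Cycs in G77S versus KO changed sign to 0.02 on log2(TPM + 1) from -1.26. The median of all genes was 0.340 there and 0.099 in the main fit, so relative to other genes Cycs stayed lower, but by a smaller margin. Where construction does not show it, the cause was not tested.

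With each library left out in turn, KO versus WT gave 0 (without KO replicate 2) to 29 (without KO replicate 1) higher and 0 (without KO replicate 2) to 15 (without WT replicate 1) lower genes. At 0 and 0 with edgeR, 1366 genes had an unadjusted p under 0.05. Without WT replicate 2 the counts were 1 and 1, without WT replicate 3 they were 8 and 2, and without G77S replicates 1, 2 and 3 they were 6 and 3, 4 and 2, and 6 and 4. A lone KO library is assumed to vary like the other groups. G77S versus WT ran from 31 (without G77S replicate 1) to 263 (without WT replicate 1) higher and 51 (without G77S replicate 2) to 375 (without WT replicate 1) lower. Without WT replicates 2 and 3 these counts were 74 and 148, and 88 and 148, without G77S replicate 2 there were 35 higher, without replicate 1 there were 97 lower, and without replicate 3 they were 73 and 110. G77S versus KO ran from 57 (without KO replicate 2) to 420 higher and 91 (without G77S replicate 2) to 529 lower, both highest without WT replicate 1. Without KO replicate 1 these counts were 102 and 124, without KO replicate 2 there were 120 lower, and without G77S replicates 1 and 3 they were 70 and 149, and 91 and 152, with 70 higher without G77S replicate 2. Called lists ran from 3 (without WT replicate 1) to 11 (without KO replicate 1) in KO, with 5 without KO replicate 2, and in the other comparisons 7 to 9, and 8 to 10. The correlation ran from 0.345 (without KO replicate 2) to 0.553 (without WT replicate 3) and the covariance from 1.342 to 2.319. Genes higher in both ran from 0 (without WT replicate 2 or KO replicate 2) to 17 and lower in both from 0 to 6, both highest without WT replicate 1. Without G77S replicates 1, 2 and 3, the numbers higher in both were 1, 1 and 2. In KO the primitive endoderm and epiblast lists kept their calls in 13 of 15 alternatives, all but the estimated correlation and fry. The list test was not run under the stricter filter, where the epiblast median reversed to -0.16 (9 of 19 positive) and the primitive endoderm median was 1.85. The 2-cell list in KO lost its call without WT replicate 3, without KO replicate 2 and with the block, while the trophectoderm list also lost its call without WT replicate 1, without KO replicate 2, with the Y-linked term and in the 6 libraries (highest adjusted p = 0.299). Depth and spread limit genes without a call, since 23.9% of simulated 4-fold changes were called in KO versus WT.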

Other observations

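The flanking test and the search for genes absent from 3 libraries were chosen after the data were seen, and the flanking test's excluding bound was rewritten after its result was seen. Cd74, an antigen presentation gene of blood cells, had 0.265 to 13.5 CPM and Muc1, of uterine epithelium, 0.232 to 4.85 CPM. Of the granulosa list, Bex4 had 1.43 to 19.4 CPM, Amhr2 1.27 to 13.6 CPM, and Hsd17b1 2.31 to 3.73 CPM in G77S against at most 0.0463 CPM in WT. The list had 5 tested genes and camera adjusted p-values of 0.982 in KO and 0.597 in G77S against WT. The uterine and blood lists had 2 tested genes each and were too short for the list test. Zp2, an egg coat gene chosen after its values were seen, had 22.3 CPM in WT replicate 3 and at most 3.55 CPM elsewhere. Khdc3, another maternal gene, had 422 to 528 CPM in the WT and KO libraries and 914, 971 and 1180 CPM in G77S. B2m, of antigen presentation, had 574 ± 239 CPM in KO and 185 ± 77.8 in WT (adjusted p = 0.186), and the interferon list had a median of 1.11 in KO (camera adjusted p = 0.0992). The germline list, whose genes are silenced by DNA methylation, had medians of -0.03 in KO and -0.21 in G77S (camera adjusted p = 0.337 and 0.768). Xist, expressed from the inactive X, had 127 CPM in WT replicate 1 and 24.1 in G77S replicate 1, and at most 5.26 CPM in the 6 libraries with Y-linked RNA.

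Dhrs7, which had 0 counts in every WT library and at least 2 CPM in the 5 others, lies 12.1 Mb from Isca2 on chromosome 12. It was the only such gene for the WT set, and of the 56 ways to choose 3 libraries 1 other gave 1 gene and the G77S set gave 2. One hypothesis is that strain variants linked to the mutant alleles may alter genes near Isca2. Within 20 Mb of Isca2, 8 of 232 genes (3.45%) had an unadjusted p under 0.01 in KO versus WT, against 613 of 13720 elsewhere (4.47%; one-sided Fisher's exact p = 0.816). The odds ratio of 0.764 had a 95% interval of 0.324 to 1.54, which leaves the hypothesis open for single genes such as Dhrs7. Efcab10, like Dhrs7 called higher in both KO and G77S (log2 fold changes 5.77 and 4.79), also lies on chromosome 12, outside this window. Over the whole chromosome, 18 of 511 genes (3.52%) passed that p in KO versus WT, against 4.49% elsewhere.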
